A study of Mus musculus with 2239 samples.

How the data were processed

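Spleen tissue of Foxp3 reporter mice was dissociated, live TCR beta-positive, CD4-positive, reporter-positive cells were sorted, and single cells were encapsulated with the inDrops protocol, per the labels' protocols. Messenger RNA was reverse transcribed from its poly(A) tail inside droplets, amplified by in vitro transcription and sequenced on an Illumina NextSeq 500, per the labels. The submitters' processing notes name TopHat2 and SAMtools, with no versions, and the mm10 build; the role and settings of each, and the gene annotation used for counting, were not given in the sources used here. The authors deposited 1 table of UMI counts, whole numbers per gene and cell with no normalization, with 23725 gene rows and 2239 cells whose column names are the sample titles. Per the labels each sample is 1 cell of 1 library, so the library is the only replicate. The total of each cell in the table was below the UMI number in its label in all 2239 cells, by a median of 1.49%. Mitochondrially encoded genes and T cell receptor genes were not analysed here, and a planned limit of 10% mitochondrial UMIs was therefore not applied. Of 263 list entries fixed, 12 were not analysed here: T cell receptor, immunoglobulin and hemoglobin genes, and older symbols of genes measured under another name. Of the gene symbols, 22627 matched the RefSeq annotation of GRCm38, the build called mm10, from which coordinates were taken.

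Cells with at least 500 UMIs were kept, which left 2055 and set aside 184. Counting noise is large at this depth: a median of 974 UMIs per kept cell means that most genes are missed in most cells that express them, and levels were read from UMIs pooled over cells. Levels are CPM, UMIs scaled to a pooled total of 1000000. Intervals are exact Poisson for levels, exact binomial (Clopper-Pearson) for shares and exact conditional (Clopper-Pearson) for ratios, all at 95%. A count of 0 was set to a floor of 3 UMIs over the class when a ratio was formed. Such ratios are bounds for that floor only, and the lower limit of the exact interval is given beside them. Droplet data hold free RNA, so shares of cells with a UMI are given with the share in B cell-like cells for T cell and Treg genes.

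Cells were clustered on analytic Pearson residuals (overdispersion 100) of the 1000 most variable genes seen in at least 10 cells, with 15 principal components, a shared-neighbor graph of 20 neighbors and the Leiden algorithm at resolution 0.8. Readout lists, ribosomal protein genes and T cell receptor segments were left out of the features, so that the lists did not define the classes. Clusters were named from 13 marker lists (resting Treg, activated Treg, proliferating, conventional T, CD8 T, NK/ILC, B cell, plasma cell, myeloid, neutrophil, erythroid, epithelial, and stromal and endothelial cells). A name needed at least 3 detected markers, each with at least 5 UMIs, at least 3 of them 1.5-fold or more above all other cells and a median ratio of at least 1.5, with 10 CPM added on both sides; the highest median won and neutrophil names were merged into myeloid. These naming thresholds were set after the data were seen. Doublets were kept. Scrublet, run through scanpy, called 3 of 2055 cells (0.146%) at an expected rate of 5%, too few to show that it could find them, and leaving those 3 out is an alternative.

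Levels in the activated Treg-like class were compared with the resting Treg-like class as ratios, with no test. The 14 readout lists were Treg identity, pan-T, suppressive effector, tissue homing, colonic Treg, transcription factors, S100 and cytoskeleton, NF-kB, interferon, immediate early, heat shock, MHC class I, glycolysis and sex-linked genes. A list member was measured with at least 20 UMIs over both classes, and counted as higher or lower at 1.5-fold. The median log2 ratio of a list was set beside 10000 random lists of the same size matched on expression among the genes that were not clustering features. Named genes were, among genes that were neither features nor ribosomal with at least 50 UMIs over both classes, the 12 with the highest and the 12 with the lowest ratio, the 3 members of each list with the largest log2 ratio in size, and Foxp3, Cd4, Cd3e, Xist and Ddx3y; further genes named were chosen after their values were seen, and some genes that the rule named are not reported here. Comparisons of lists between a single cluster and the other T cells, which also needed 5 UMIs expected in the cluster, were added after the data were seen. Co-variation is the mean pairwise Pearson correlation of a list's members across cells, from Pearson residuals, beside 10000 matched random lists.

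The ratio step was run on simulated Poisson counts drawn from the pooled levels of both classes at their real totals. It covered 1503 genes that were not ribosomal and had at least 50 UMIs over both classes, 200 of them changed. Past 1.5-fold in the simulated direction were 56.7% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 100.0% of those changed 4-fold. Of 1303 unchanged genes 9.36% also passed 1.5-fold by counting noise, and 96.4% of intervals held the simulated ratio. The intervals assume the same independent counts that were simulated, so this coverage checks the calculation only. UMIs that gather in few cells, and list genes taken at 20 UMIs, were not simulated, so both figures may be too favorable for them. The co-variation step put 0 of 14 lists above the random range on independent counts, and 1, the intended list, when the interferon genes were given a shared factor.

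The groups, lists, filters, clustering settings, rule for named genes and the alternatives that follow were fixed before the data were examined. The alternatives changed the UMI minimum (300 and 1000), mitochondrial limit, doublet treatment, depth, resolution, number of variable genes and components, value scale, random seed, features, the use of the same UMIs for clustering and measuring, the averaging of cells and the list minimum. Others were added after the data were seen: leaving ribosomal UMIs out of the total, comparing the activated class with all other T cells, and leaving out the B cell, myeloid and NK/ILC-like cells. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, scanpy 1.11.5 and matplotlib 3.10.9.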

Results

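The data are single-cell transcriptomes of mouse regulatory T cells (Tregs), the CD4 T cells that carry the transcription factor Foxp3 and restrain immune responses. The cells came from a male B6 mouse or mice aged 7 months, carried a green fluorescent reporter of Foxp3, and were sorted as live, TCR beta-positive, CD4-positive and reporter-positive. All 2239 labelled samples were single cells of 1 library with the tissue label spleen. Its sample type label also names the colon, and the labels do not settle whether colon cells were loaded with the spleen cells. The library was made with inDrops, a droplet method that tags each captured mRNA molecule with a unique molecular identifier (UMI). Because there was 1 library, no value below has a replicate, no test between groups was possible, and every interval is a 95% interval for counting error only. Libraries of conventional T cells and of other tissues were not analysed here.

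The cells were shallowly sampled. The table held 2226960 UMIs over 13025 detected genes, with a median of 938 UMIs per cell and a median of 540 genes per cell. Of the reads in the labels, 62.4% were mapped, and each UMI rested on 3.82 mapped reads. The 2055 cells with at least 500 UMIs (91.8%) were kept; they had medians of 974 UMIs and 551 genes. Ribosomal protein genes took 36.0% of their UMIs, and the most abundant single gene, Tpt1, took 1.396% of all UMIs.

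The first question was whether the transcripts matched the sort. Foxp3, on chromosome X from 7579676 to 7595243 in GRCm38, had a UMI in 595 of the 2055 kept cells (29.0%, exact binomial interval 27.0 to 31.0), at 371.5 CPM (346.2 to 398.1), where CPM are UMIs scaled to a pooled total of 1000000. Other genes of the Treg program were seen in shares on both sides of this: Ikzf2, which encodes the transcription factor Helios, in 39.1% of cells, Izumo1r, which encodes folate receptor 4, in 38.2%, Il2ra, the high-affinity interleukin 2 receptor chain, in 36.3%, and Tnfrsf18, which encodes GITR, in 26.6%. The other 7 measured members of the list had smaller shares, Nrp1 in 21.8%, Capg in 11.9%, Gpr83 in 10.9%, Ctla4 in 10.5%, Lrrc32 in 10.4%, Socs2 in 10.2% and Ikzf4 in 4.62%. The T cell genes Lck, Thy1 and Cd3d had a UMI in 51.2%, 37.3% and 36.8% of cells, and Cd4 in 19.5% (17.8 to 21.3). Of the conventional T cell markers, Il2, Il17a and Il21 had no UMI in the 2055 cells, which allows a share of up to 0.179% of cells with a UMI for each. Cd40lg was seen in 3 cells and Ifng in 6, while Il7r, the interleukin 7 receptor chain, was seen in 12.1% of cells. Of the CD8 genes Cd8a was seen in 4 cells and Cd8b1 in 74 (3.60%, 2.84 to 4.5), against 2.30% of B cell-like cells for Cd8b1.

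The background of these shares was read from B cell-like cells, which should lack Foxp3. In 87 such cells, with a median of 907 UMIs, Foxp3 had a UMI in 3.45% (0.717 to 9.75), Cd4 in 1.15% and Cd3d in 1.15%. Lck had a UMI in 6.90% of them, Ikzf2 and Tnfrsf18 each in 4.60%, Thy1, Izumo1r and Gpr83 each in 3.45%, Il2ra and Nrp1 each in 2.30% and Ikzf4 in 1.15%. Ctla4, Lrrc32, Socs2 and Il7r had none in the 87 cells, which allows a share of up to 4.15%. Capg had a UMI in 16.1% of the B cell-like cells (9.09 to 25.5), so its share of 11.9% was not above theirs. Myeloid markers summed to 1827 CPM in the B cell-like cells against 112 in cells outside the B cell, myeloid and NK/ILC-like classes. Of those 170 UMIs in the B cell-like cells 125 were of Cst3, with 44 and 41 in its highest cells. The rise was not of Cst3 alone, as 7 of 9 detected myeloid markers were at least 1.5-fold up there. The B cell-like class is therefore not a clean measure of free RNA, and its Capg share may not be background. With every kept cell thinned to 500 UMIs, the Foxp3 share was 16.7% and the Cd4 share 10.8%. Among genes of the sex chromosomes, Ddx3y, a Y-linked helicase gene, had a UMI in 11.4% of cells, Eif2s3y in 6.08%, Uty in 1.85% and Kdm5d in 1.12%. Xist, the X-inactivation RNA of female cells, had none in 2055 cells (up to 0.179%). Erythroid genes were nearly undetected, with Hba-a2 in 5 cells. Of the epithelial markers Epcam alone was seen, in 39 cells (1.90%, with 1.15% of B cell-like cells), and of the stromal and endothelial markers Pecam1, in 180 cells (8.76%, with 6.90% of B cell-like cells), made up nearly all UMIs.

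The second question was which kinds of cells the sort held. Clustering gave 13 clusters, of which 6 could be named from fixed markers. A resting Treg-like cluster held 396 cells (19.3%, 17.6 to 21.0) and was led by Myo6, Ly6c2, Ly6c1, Klf3 and the marker Igfbp4; 7 of its 8 detected markers were at least 1.5-fold above all other cells. An activated Treg-like cluster held 134 cells (6.52%, 5.49 to 7.68), with Klrg1, Icos and Maf among its leading genes and all 7 detected markers at least 1.5-fold up. In that cluster 7 of the 10 proliferation markers were also at least 1.5-fold up. A proliferating-like cluster led by histone genes and Rrm2 held 70 cells (3.41%, 2.66 to 4.28). The remaining 7 clusters, with 1286 cells (62.6%, 60.4 to 64.7), stayed unnamed under a naming threshold that was set after the data were seen.

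Cells with markers of B cells and myeloid cells were present despite the gate. B cell-like cells, led by H2-Aa, Cd74, Cd79a and Ms4a1, made up 4.23% of kept cells (3.41 to 5.20). In that cluster 7 of the 9 detected myeloid markers were also at least 1.5-fold up. Myeloid-like cells, 53 in number and led by the neutrophil genes S100a9, S100a8 and Retnlg with Lyz2 and Tyrobp, made up 2.58% (1.94 to 3.36). S100a8 was seen in 13 of them and Tyrobp in 24, while Ikzf2 was seen in 30.2% and Foxp3 in 13.2%, with pan-T genes at 0.515 times (0.423 to 0.621) the level of the T cell clusters. Another 29 cells (1.41%, 0.947 to 2.02) were NK/ILC-like, led by Gzma, Ccl5, Nkg7, Klrb1c and Ncr1. Ccl5 and Nkg7 belong to the CD8 T cell list, and pan-T genes in these 29 cells stood at 1.002 times (0.840 to 1.19) the level of the T cell clusters, with a Foxp3 UMI in 24.1% of them, so they were not shown to be of another lineage. Together the 3 classes held 169 cells (8.22%, 7.07 to 9.50). The B cell-like share stayed between 4.14% and 4.45% under the alternatives that gave class shares. The activated Treg-like share did not: it ran from 6.38% to 17.7% over the alternatives, and the resting share from 15.9% to 41.5%, with no resting class named at 300 UMIs or with log values. Membership moved too: of the 396 resting Treg-like cells 140 were in the resting class with 30 components, 200 with 10 components and 194 with readout lists as features.

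**Figure D1:**
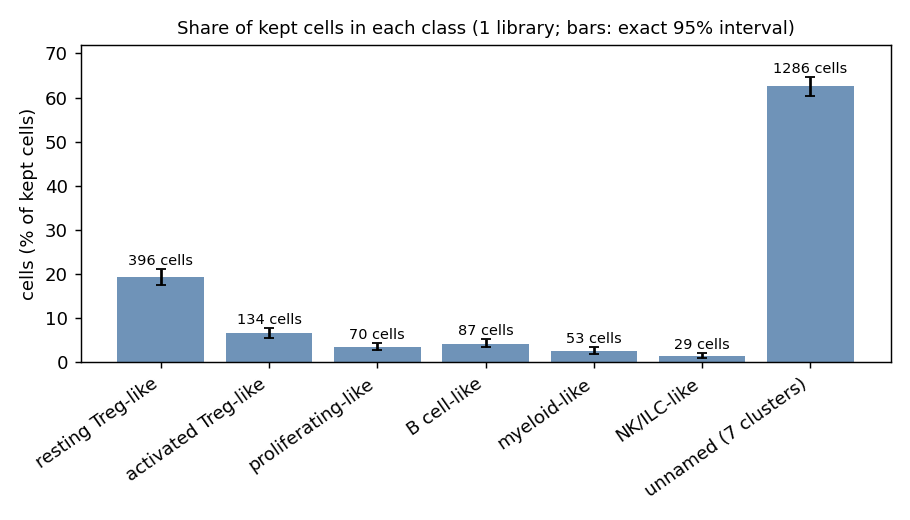
Share of the 2055 kept cells (vertical axis, percent) in each class of the single library; error bars are exact binomial 95% intervals and numbers above bars are cells. The unnamed clusters held 62.6% of cells, and the activated Treg-like class 6.52%.

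Gene lists that had been kept out of the clustering set some clusters apart. In unnamed cluster 3, with 267 cells, 13 of 15 interferon-stimulated genes were at least 1.5-fold above the other T cells, with a median log2 ratio of 0.88. Ifit3 was 5.31-fold higher (2.75 to 10.1), Ifit1, an antiviral RNA-binding protein gene, 5.19-fold (3.49 to 7.66) and Usp18 3.17-fold (1.75 to 5.52), while Gbp2 stood at 1.37-fold (0.892 to 2.05). Other interferon-stimulated genes such as Ifit3b were clustering features, so the list was not independent of that cluster. In unnamed cluster 4, with 191 cells, 4 of 8 immediate early genes were at least 1.5-fold higher, with Egr1 at 3.56-fold (2.15 to 5.72) and Nr4a1, which responds to T cell receptor signals, at 3.09-fold (2.14 to 4.37). In the B cell-like cluster all 10 pan-T genes were lower, with a median log2 ratio of -3.73, and 10 of 11 Treg identity genes were lower, with a median of -2.65.

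**Figure D2:**
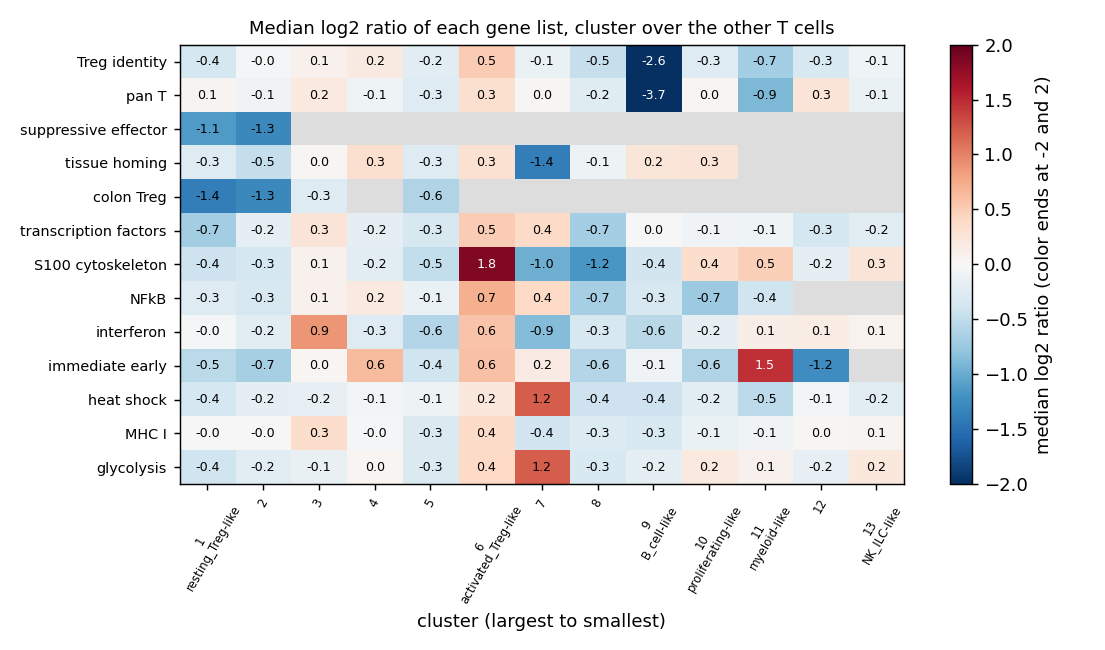
Median log2 ratio of each gene list (rows) in each of the 13 clusters (columns) over the other cells outside the B cell, myeloid and NK/ILC-like classes; red is higher, blue lower, and grey marks lists with fewer than 3 measured genes. The interferon list reached 0.88 in cluster 3 and the S100 and cytoskeleton list 1.85 in the activated Treg-like cluster.

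The third question was how the activated Treg-like cells differed from the resting Treg-like cells. The activated class expressed far more of the S100 and cytoskeleton genes. S100a4, a calcium-binding protein gene of motile cells, had 202 UMIs in the activated class and 0 in the resting class. That was 175-fold higher against a floor of 3 UMIs over the class, with an exact lower limit of 141. S100a6 was 152-fold higher (58.5 to 561.6), with 233 and 4 UMIs, and S100a11 21.3-fold higher (9.11 to 60.8). The chemokine receptor gene Ccr2 was 44.3-fold higher against that floor (exact lower limit 34.7), with 51 and 0 UMIs. These sizes depended on the settings: over the alternatives the log2 ratio of S100a4, 7.46 here, ran from 2.24 to 9.42, that of S100a6, 7.25 here, from 1.99 to 7.69, that of S100a11, 4.41 here, from 1.87 to 4.66, and that of Ccr2, 5.47 here, from 4.25 to 6.88 with no value at 1000 UMIs. Foxp3 differed little, with 476.2 against 417.0 CPM, a ratio of 1.14 (0.851 to 1.52) and a log2 ratio of 0.19 that became -0.06 with ribosomal UMIs left out of the total. These ratios compare 149107 UMIs of 134 cells with 388463 UMIs of 396 cells. Of the 134 activated cells 49 had a UMI of S100a4, 52 of S100a6 and 22 of Ccr2.

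Of 103 list genes measured in this contrast, 52 were at least 1.5-fold higher in the activated class and 3 lower. The total itself shifted: ribosomal protein genes took 25.6% of UMIs in the activated class and 37.4% in the resting class, and their median log2 ratio was -0.53. With ribosomal UMIs left out of the total, a scaling chosen after the data were seen, every log2 ratio moved by -0.25, the counts became 42 higher and 8 lower, and the median of genes eligible for naming moved from 0.24 to -0.01. List medians are therefore given on the total first and on this second scale after it.

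Among S100 and cytoskeleton genes, 10 of 12 were at least 1.5-fold higher and none lower (median log2 ratio 1.86, then 1.61, above all 10000 random lists matched on expression). Ahnak, which encodes a large scaffold protein, was 9.44-fold higher (5.95 to 15.5; log2 ratio 0.01 with a minimum of 1000 UMIs per cell), Itgb1, the integrin beta 1 chain, 7.22-fold (4.37 to 12.3) and Lgals1, which encodes galectin 1, 4.05-fold (3.04 to 5.43). Tmsb10 stood at 0.719 (0.655 to 0.789), and was the 1 member past 1.5-fold lower on the second scale. With a minimum of 1000 UMIs per cell this list's median was -0.17; the class named activated at that minimum drew 68 of its 134 cells from unnamed cluster 7 and 33 from the class described here.

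Treg identity genes split. Of 12 measured, 6 were at least 1.5-fold higher and 1 lower, then 6 and 2 (median 0.65, then 0.40, percentile 99.6 of random lists). Ctla4, an inhibitory receptor of Tregs, was 5.76-fold higher (3.77 to 8.98), Ikzf2 3.83-fold (3.11 to 4.74), Capg 3.52-fold (2.29 to 5.43) and Tnfrsf18 2.74-fold (2.05 to 3.67). Gpr83, a receptor gene of resting Tregs, was lower at a ratio of 0.141 (0.0374 to 0.376; log2 ratio -2.83, and -0.72 at 1000 UMIs), and Il2ra stood at 1.03 (0.786 to 1.34), below 1 on the second scale. Pan-T genes were higher in 5 of 10 (median 0.48, then 0.23, percentile 92.4), with Cd3e at 1.99 (1.18 to 3.31), Thy1 at 1.63 (1.29 to 2.04; log2 ratio -0.0775 at 1000 UMIs), Cd3g at 1.59 (1.22 to 2.06) and Cd4 at 1.55 (1.09 to 2.17); on the second scale 1 was past 1.5-fold higher and 1 lower, the latter being Cd247, which stood at 0.778 (0.568 to 1.05) on the first.

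Transcription factor genes also moved both ways: 5 of 9 were higher and 2 lower, then 5 and 3 (median 0.98, then 0.73, percentile 99.9). Id2, an inhibitor of basic helix-loop-helix factors, was 27.8-fold higher (8.69 to 141.8) with 32 and 3 UMIs. Batf, needed for effector Treg differentiation, was 7.63-fold higher (4.07 to 15.2), Ikzf3 6.84-fold (2.91 to 17.8) and Gata3 2.16-fold (1.63 to 2.85). Foxp1 and Bach2, which hold T cells in a resting state, were lower, at 0.423 (0.282 to 0.617) and 0.244 (0.0479 to 0.781). With a stricter minimum of 100 UMIs per list member, the median of the list was -0.53, and with cells clustered on one random part of their UMIs and levels measured on the other it was -0.15.

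Suppressive effector genes and colonic Treg genes were mostly below the 20 UMIs required, and 3 of each list were measured. Fgl2, a secreted suppressor, was 107-fold higher (18.1 to 4321) with 41 and 1 UMIs. Gzmb, which encodes granzyme B, was 22.6-fold higher against the floor for a count of 0 (26 and 0 UMIs, exact lower limit 17.1). Its 26 UMIs lay in 10 of the 134 activated cells. Nt5e, which encodes the ectoenzyme CD73, was 3.44-fold higher (1.98 to 6.03). In the colonic list Penk, which encodes the opioid precursor proenkephalin, was 159-fold higher (27.5 to 6379), with 61 and 1 UMIs. Of those 61 UMIs 36 lay in 1 cell, and 13 of 134 activated cells had any. Penk was also among the leading genes of unnamed cluster 7, and its log2 ratio, 7.31 here, was 3.87 against all other T cells. Gata3 and Gzmb are on more than 1 list. Both medians, 4.497 and then 4.248, sat on the bound of Gzmb; over the alternatives they ran from 2.94 to 5.84 and from 2.94 to 6.29, with no value at 1000 UMIs, with UMIs split or with 100 UMIs per member. Il1rl1, which encodes the interleukin 33 receptor, had a UMI in 13 of 2239 cells. Of 4 tissue homing genes Ccr2 alone passed 1.5-fold (median 0.34, then 0.10, percentile 64.0), with Itga4 at 1.48 (0.910 to 2.35) and Itgb7 at 0.911 (0.628 to 1.30).

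Of the remaining lists, NF-kB, immediate early and glycolysis genes had higher medians than most random lists, and interferon, heat shock and MHC class I genes less clearly so. That order holds against the resting class. Against all other T cells, with random lists that could include clustering features, the interferon list stood at percentile 98.5 and the glycolysis list at 80.3. NF-kB and immediate early genes stayed high there, at 99.0 and 97.7. NF-kB pathway genes were higher in 5 of 7, then 4 (median 0.84, then 0.59, percentile 99.1), including Nfkb1 at 2.04 (1.48 to 2.81) and its inhibitor gene Nfkbia at 1.76 (1.43 to 2.16), with Traf1 at 1.44 (0.803 to 2.52). Immediate early genes were higher in 5 of 9 on both scales, with 1 lower on the second (median 1.24, then 0.995, percentile 99.98; 0.33 with 30 components and 0.51 with UMIs split), with Junb at 3.78 (2.59 to 5.55), Zfp36 at 1.25 (0.735 to 2.07) and Btg2 at 0.755 (0.435 to 1.26). Glycolysis genes were higher in 4 of 7, then 2 (median 0.69, then 0.45, percentile 96.5), with Gapdh at 2.27 (1.67 to 3.09), Pkm at 1.62 (1.17 to 2.23) and Pgk1 at 1.48 (0.910 to 2.35). Interferon genes were higher in 4 of 13, then 3 (median 0.44, then 0.19, percentile 86.1; -0.43 with a minimum of 1000 UMIs per cell), with Bst2 at 2.19 (1.33 to 3.61) and Ifi27l2a at 2.13 (1.72 to 2.63; log2 ratio -0.0916 at 1000 UMIs). Heat shock genes were higher in 3 of 8, then 2 (median 0.49, then 0.24, percentile 89.8), with Hspd1 at 1.99 (1.15 to 3.42) and Dnajb1 at 1.55 (0.906 to 2.60; log2 ratio -0.0514 with 500 variable genes). No MHC class I gene of 8 reached 1.5-fold (median 0.39, then 0.14, percentile 81.3), the highest being Psmb8 at 1.42 (1.11 to 1.80).

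Over the alternatives the medians of the other lists ran from 0.18 to 1.21 for Treg identity, 0.17 to 0.63 for pan-T, -0.17 to 1.29 for tissue homing, -0.53 to 1.07 for transcription factors, -0.17 to 2.11 for S100 and cytoskeleton, 0.58 to 1.37 for NF-kB and -0.43 to 0.84 for interferon genes. They ran from 0.33 to 1.64 for immediate early, 0.17 to 1.09 for heat shock, -0.11 to 0.49 for MHC class I and 0.40 to 0.91 for glycolysis genes. Contrasts at 300 UMIs and with log values gave no value, as no resting class was named.

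The ends of the ratio were read among genes eligible for naming. These leave out the 1000 clustering features, while list genes were never features, so the ends are not those of all genes. Among eligible genes outside these lists, Hacd3 was 5.52-fold higher (3.02 to 10.5), Vmp1, an autophagy gene, 5.07-fold (2.79 to 9.50) and Plekhb2 4.92-fold (2.70 to 9.26). Treml2 had the lowest ratio of the eligible genes, 0.0814 (0.00965 to 0.306), with 2 and 64 UMIs. Its log2 ratio, -3.62 here, ran from -4.00 to -0.93 over the alternatives. Pip4k2a stood at 0.150 (0.0300 to 0.464), Ndrg3 at 0.189 (0.0594 to 0.462), Pdlim1 at 0.197 (0.0517 to 0.534) and Nsg2 at 0.237 (0.110 to 0.452), with highest log2 ratios over the alternatives of -0.33, -0.84, -0.87 and -0.36. Map4k4, Wdr89, Mrpl30, Aven, Chchd10 and Rtf1 lay between 0.289 and 0.355, but Chchd10 turned to a log2 ratio of 0.20 at 1000 UMIs and Rtf1 to 0.51 with UMIs split. Ddx3y, on the Y chromosome, stood at 0.886 (0.479 to 1.56), and Xist had no UMI in either class.

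Markers of other cell types were also higher in the activated class, beside every group above. B cell markers summed to 107 CPM against 18.0 in the resting class, myeloid markers to 275.0 against 87.5 and CD8 T cell markers to 154 against 59.2. Of the 41 myeloid-list UMIs in the activated class 30 were of Cst3, 1 in each of 30 cells. Cst3 was seen in 10.2% of all cells outside the B cell, myeloid and NK/ILC-like classes. A single UMI of it therefore does not by itself mark a myeloid cell. Its level was still higher in myeloid-like cells, at 1092 CPM against 103.7 in those other cells. A small myeloid part of the activated class therefore stays open. The epithelial list summed to 80.5 against 2.57, all of it Epcam (12 and 1 UMIs). Of the neutrophil genes, S100a8 had 15 UMIs in the activated class, all in 1 cell. NK/ILC markers stood at 13.4 against 5.15 and plasma cell markers at 13.4 against 2.57, on 2 UMIs or fewer each, and stromal and endothelial markers were lower, at 46.9 against 85.0.

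**Figure D3:**
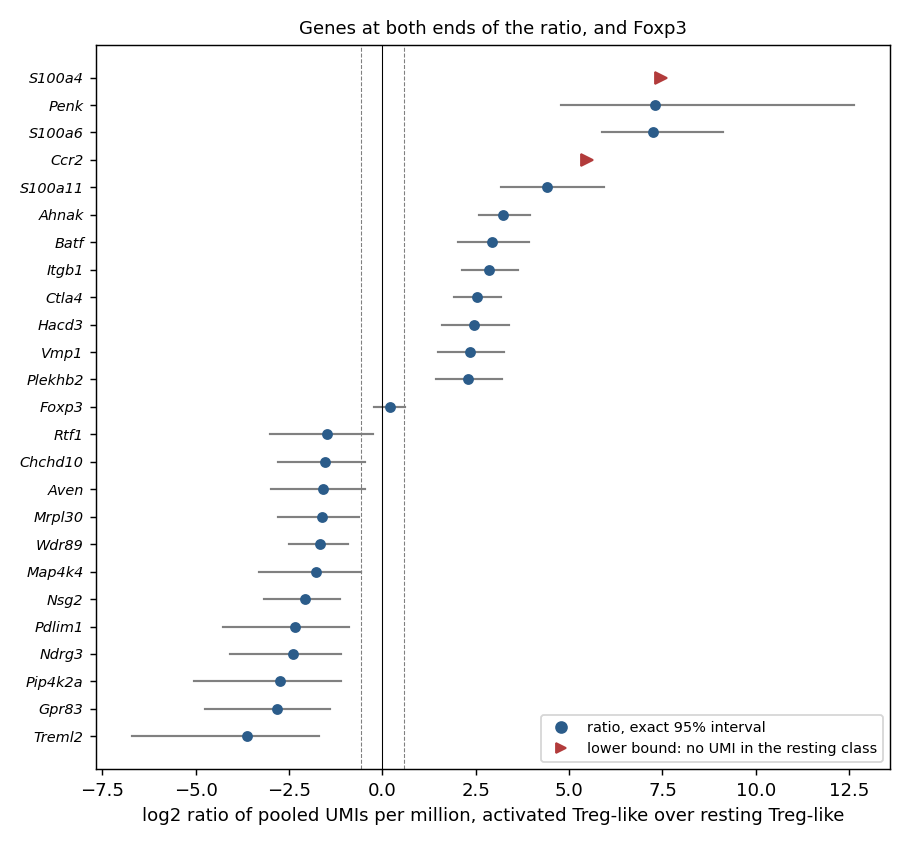
Log2 ratio of pooled CPM (horizontal axis), activated Treg-like over resting Treg-like class, for the 12 highest and 12 lowest eligible genes and Foxp3. Points are ratios with exact 95% counting intervals, and dashed lines mark 1.5-fold. Arrowheads, labelled as lower bounds in the figure, are ratios with a count of 0 set to 3 UMIs. S100a4 sits at 7.46 against that floor and Treml2 lowest at -3.62, while the interval of Foxp3 spans 0.

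The last question was which gene groups varied together from cell to cell. Immediate early genes had the highest mean pairwise correlation across the 2055 cells, 0.108, with the middle 95% of matched random lists between -0.0063 and 0.0071. S100 and cytoskeleton genes followed at 0.105, interferon genes at 0.0898 and heat shock genes at 0.0641. Treg identity genes reached 0.0474, glycolysis genes 0.0395, suppressive effector genes 0.0345, MHC class I genes 0.0341, pan-T genes 0.0307, NF-kB genes 0.0282, tissue homing genes 0.0140 and transcription factors 0.0081. Those 12 lists lay above the range of random lists. The colonic Treg list (0.0084, percentile 87.8) and the sex-linked list (-0.0012, percentile 46.3) did not. Without the B cell, myeloid and NK/ILC-like cells, S100 and cytoskeleton genes ranked first at 0.120 with immediate early genes at 0.107. That S100 value rests on 13 members against 15 over all kept cells, so the members changed as well as the cells. The pan-T value fell to 0.0103 and the Treg identity value to 0.0372, and 12 lists again lay above their range. Cells are not replicates, and the percentiles describe this library only.

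**Figure D4:**
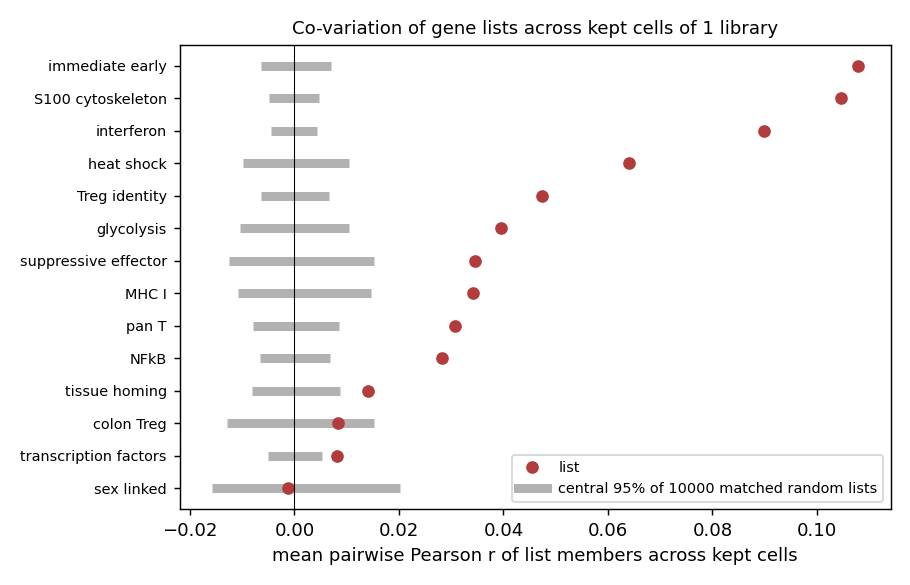
Mean pairwise Pearson correlation of list members across kept cells (horizontal axis) for each of 14 lists; points are the lists and grey bars hold the middle 95% of 10000 random lists matched on expression. Immediate early genes sit highest at 0.108, and the colonic Treg and sex-linked lists lie within their bars.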

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

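All tests in this part on cells under 500 UMIs were chosen after the data were seen. The 184 cells below the minimum of 500 UMIs held 70683 UMIs, with a median of 402.5 per cell. They carried signal above the 52.2 CPM that a count of 0 allows. Foxp3 stood at 410.3 CPM (exact Poisson interval 274.8 to 589.2) against 371.5 in kept cells, a ratio of 1.10 (0.735 to 1.60). Pan-T genes summed to 4089 against 3813 CPM, a ratio of 1.07 (0.9503 to 1.21). B cell markers summed to 990.3 against 1041 (ratio 0.952, 0.739 to 1.21). Myeloid markers were higher in the shallow cells, at 679.1 against 398.4 (ratio 1.70, 1.25 to 2.28), while neutrophil markers were lower, at 99.0 against 260.6 (ratio 0.380, 0.152 to 0.788). NK/ILC markers, on 4 UMIs, stood at 56.6 against 29.7 (ratio 1.91, 0.504 to 5.12), and erythroid genes had no UMI. No explanation of these values was tested.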

How the results depend on the processing

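Ribosomal scaling, the comparison with all other T cells and leaving out B cell, myeloid and NK/ILC-like cells were chosen after the data were seen. The limit of 5% mitochondrial UMIs was not run, as it had no genes to act on. With 300 UMIs and with log values no resting class was named, so the contrast gave no value; NK/ILC-like cells went unnamed there too, proliferating-like cells with log values and 30 components, and myeloid-like cells with 1000 UMIs. No paired analysis was possible because there was 1 library.

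With at least 1000 UMIs, 944 cells were kept; Foxp3 was seen in 31.6%, the classes were resting 25%, activated 14.2%, proliferating 16.5% and NK/ILC 5.19%, and 33 list genes were higher and 15 lower in the activated class, which drew 68 of 134 cells from cluster 7. There the S100 and cytoskeleton median was -0.17, Chchd10 0.20, Thy1 -0.0775 and Ifi27l2a -0.0916 (log2), all reversed, and Ahnak lost its difference (0.01). Medians with no call also turned: interferon to -0.43, tissue homing to -0.17 and MHC class I to -0.11 there, and interferon to -0.00287 without called doublets. Thinning to 500 UMIs gave Foxp3 in 16.7%, by construction. The resting share was 41.5% at resolution 0.5, 15.9% at 1.2, 16.3% with 500 variable genes and 21.1% with 10 components. The activated share was 17.7% with 300 UMIs, 7.74% at resolution 1.2, 15.5% with 500 variable genes, 17.3% with 10 components, 11.0% with log values and 7.83% with seed 1; the larger classes took in cells of cluster 3 (112 of 393 with 300 UMIs). The proliferating share was 5.60% with 10 components. The myeloid share was 3.89% with 30 components, 1.07% with log values and 1.85% with readout lists as features, and the NK/ILC share 0.876% with 2000 variable genes and 0.730% with 30 components. For shares the cause was not tested.

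Against 52 higher and 3 lower, members with 100 UMIs gave 21 and 1, by testing fewer genes. The number lower was 5 without called doublets, 7 at resolution 0.5, 6 with 2000 variable genes, 8 without ribosomal UMIs and 8 against all other T cells. The transcription factor median reversed to -0.15 with UMIs split and -0.53 with 100 UMIs, Rtf1 to 0.51 with UMIs split and Dnajb1 to -0.0514 with 500 variable genes; the cause was not tested. Of the other values of list medians 149 stayed within their counting interval and 34 did not, and of gene ratios 704 and 85. Lowest log2 ratios over the alternatives were 2.24 for S100a4, 1.99 for S100a6, 1.66 for Batf, 1.55 for Ctla4, 0.78 for Ikzf2, 0.56 for Plekhb2 and 0.01 for Ahnak. All 5 co-variation alternatives put 12 lists above the random range.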

Other observations

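The list comparisons by cluster, the random placements and split by depth of Foxp3, and the tests of free RNA, of doublets and of dissociation stress were chosen after the results were seen; the tests of expected depth and of conventional T cells were written with the Foxp3 share known but not the value tested.

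A group of 105 cells, unnamed cluster 7, had high levels of heat shock and glycolysis genes and low levels of S100 and interferon genes. Of 8 heat shock genes 6 were at least 1.5-fold above the other T cells (median log2 ratio 1.22): the mitochondrial chaperone gene Hspd1 3.56-fold (2.66 to 4.72), Hsp90aa1 3.28-fold (2.69 to 3.98) and Hspe1 2.72-fold (2.30 to 3.20). The list members Hspa1a and Hspa1b had 1 and 8 UMIs over all kept cells, too few to be measured. The heat shock values therefore do not cover them. Of 7 glycolysis genes 6 were higher (median 1.21), with Tpi1 at 3.05 (1.70 to 5.18) and Pgk1 at 2.32 (1.64 to 3.21). Of 14 interferon genes 10 were lower (median -0.87), as were 9 of 12 S100 and cytoskeleton genes (median -0.97), with S100a4 at 0.0418 (0.00105 to 0.235) and Vim at 0.394 (0.260 to 0.574). Itgb1 was the 1 member of that list past 1.5-fold higher, at 1.79 (1.21 to 2.58), and Nfkbid, an atypical NF-kB regulator gene, was 3.67-fold higher (2.19 to 5.95). These cells had a median of 1282 UMIs, the highest of the 13 clusters. The other T cells include cluster 3, high in interferon genes, and the activated Treg-like cluster, high in S100 genes. Low medians were not particular to cluster 7: the S100 and cytoskeleton list stood at -1.16 in cluster 8 and the interferon list at -0.59 in cluster 5. S100a4 had 0 UMIs in the resting class.

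In the proliferating-like cluster 5 of 12 S100 and cytoskeleton genes were at least 1.5-fold higher, including S100a4 at 1.83 (1.10 to 2.89) and Crip1 at 1.66 (1.29 to 2.11). The myeloid-like cluster held all 5 measured immediate early genes at least 1.5-fold above the T cells, with Nr4a1 at 5.85 (3.78 to 8.75) and Zfp36 at 3.10 (1.96 to 4.71). That cluster was mixed: of its 53 cells S100a8 was seen in 13 and Csf1r in 14. In the B cell-like cluster all 475 Jchain UMIs lay in 2 cells, and 2 cells held 44 and 41 of the 125 UMIs of the myeloid marker Cst3.

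Foxp3 had a UMI in 578 of the 1886 cells outside the B cell, myeloid and NK/ILC-like classes (30.6%, 28.6 to 32.8), although every cell was sorted on its reporter. If every cell held Foxp3 RNA at the pooled level of 394.2 CPM, depth alone would give 33.1%, and 2000 random placements of the 779 UMIs by depth gave 32.2% to 34.0%. Depth at a common level would by itself leave most cells without a UMI, but it overshoots the observed share as a whole. The share rose less with depth than a common level would give: the shallowest cells had 27.7% (24.2 to 31.3) with 24.4% expected, and the deepest 34.5% (30.8 to 38.4) with 42.9% expected. Free RNA as the source of the Foxp3 UMIs is argued against by its level in B cell-like cells, 0.109 times (0.0296 to 0.280) that of the others. Conventional T cells as most of the cells without a Foxp3 UMI are argued against by the other Treg identity genes, which stood at 0.824 times (0.783 to 0.868) their level in cells with one; a smaller number of such cells stays open, and no biological explanation was tested.

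The B cell-like class of 87 cells and the myeloid-like class of 53 carried markers of cells that the gate on TCR beta and CD4 should remove. In the myeloid-like class Tyrobp was seen in 24 cells and S100a8 in 13, so not every cell of it was shown to be of another lineage. As doublets with a T cell, B cell-like cells would carry pan-T genes, but these stood at 0.0694 times (0.0453 to 0.102) their level in T cells. Of the myeloid-like cells 43.4% (29.8 to 57.7) had no UMI of any pan-T gene, against 3.45% (2.67 to 4.37) of T cells. Not every one was therefore a doublet with a T cell. Since the level in the class was 0.515 times (0.423 to 0.621) that of T cells, some may have been. That level does not tell doublets from T cells placed in the class. B cells and myeloid cells that passed the gate stay open, and no biological explanation was tested.

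For the heat shock and glycolysis genes of cluster 7, stress during dissociation was looked for in the immediate early genes. These stood at 1.21 times (1.03 to 1.41) their level in the other T cells, a smaller rise than that of the chaperones, although Nr4a1 alone stood at 2.58 (1.71 to 3.79). The pooled rise stayed under a limit of 1.5-fold, but that limit was set after the results were seen and the interval lies above 1. The test therefore cannot decide whether stress played a part, and the heat shock genes Hspa1a and Hspa1b were too sparse to compare. Doublets of cells drawn at random from the other T cell clusters would not be expected to exceed the highest of these. The pooled level in cluster 7 was 1.59 times (1.46 to 1.73) that of the next highest, the activated Treg-like cluster. Cluster 7 was singled out for high levels of these same genes, so that outcome was close to given beforehand. The comparison therefore cannot decide about doublets. No biological explanation was tested.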
